A study of Homo sapiens with 5 samples.

How the data were processed

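The data are 5 RNA-seq libraries of MDA-MB-231 cells, 1 library in each of 5 groups: LY6E-DT targeted (si-LY6E-DT), its negative control (si-NC), a library labelled as an HNRNPC knockdown, the input of an RNA immunoprecipitation and the HNRNPC immunoprecipitate. Per the labels' protocols, cells were grown in L15 medium with serum, RNA was taken with Trizol, libraries followed standard Illumina protocols, and the immunoprecipitation used a commercial magnetic bead kit.

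The deposited values are FPKM per gene, per the file headers, 1 file per library. The submitters' processing notes name FastQC 0.11.7, cutadapt 1.17, HISAT2 2.1.0 and StringTie 1.3.3 and the build GRCh37, without their roles or settings. FPKM divides fragments by gene length and by the library's total, so a gene's value also depends on what the most abundant genes take of that total, and an assembler that estimates transcripts can move reads between gene models that overlap. The low values showed no whole-read steps, so the depth is unknown and no counting interval or floor is given. No count test was used.

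The files held 12497 different gene rows, of which 10731 were listed in all 5 libraries. Both RIP tables had the same rows, as did si-LY6E-DT and si-NC, while the table labelled si-HNRNPC had 419 rows that the si-NC table lacked. The tables were thus filtered in separate sets, and the si-HNRNPC and cross-set comparisons rest on FPKM alone. Gene IDs without their version were matched to GENCODE 29: 12394 rows were protein-coding there, 14 had another type and 89 had no match. No annotation of GRCh37 was used here, so positions are those of GENCODE 29 on GRCh38 and no coordinates were converted. Rows that share exons with another coding gene on the same strand (1415) are called uncertain.

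For each contrast the change was log2((FPKM + 1)/(control FPKM + 1)), a scale that understates changes of low genes, for genes listed in both libraries with a mean FPKM of at least 1. A gene rose or fell, or was enriched or depleted, when it changed at least 2-fold on that scale. This is a rule of size, not a test, since a group with 1 library has no spread. The contrasts were si-LY6E-DT and the library labelled si-HNRNPC against si-NC, the immunoprecipitate against input, and si-NC against the RIP input, with the library labelled si-HNRNPC against the RIP input as an alternative. Named genes are the targeted genes, the 8 largest rises and 8 largest falls per contrast with a mean FPKM of at least 5, 3 examples per list apart from chance, and the genes of the intersection; exceptions are marked as chosen after their values were seen. A gene that this rule takes is not reported here. Genes of the Y chromosome, XIST and rows without a symbol were not named.

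The 30 gene lists were LY6 locus neighbours, hnRNP family, SR and core splicing factors, m6A writers, readers and erasers, interferon-stimulated genes, NF-kB targets, G2/M, S phase, mesenchymal, epithelial, extracellular matrix and proteases, TGF-beta, YAP/TAZ, p53, ATF4 and unfolded protein response, hypoxia, heat shock, cholesterol synthesis, glycolysis, oxidative phosphorylation, apoptosis regulators, ribosomal proteins, mitochondrially encoded mRNAs, histones, immediate early genes, nuclear-retained lncRNAs, KRAB zinc fingers, and luminal, fibroblast and leukocyte markers of other cell types. A list with at least 5 members passing the filter was described by the percentile of its median change among 10000 random lists of the same size, drawn from 20 bins of mean expression, and called apart below 2.5 or above 97.5. Percentiles describe these libraries and are not p-values. The contrasts, lists, and rule for named genes were fixed before the data were examined.

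Transcript length, GC content and the density of runs of 5 U in the 3' UTR came from 1 protein-coding transcript per gene in GENCODE 29. Alternatives were pseudocounts of 0.1 and 5, no filter, a filter of 5, centring on the median, quantile normalization, rescaling without mitochondrial, ribosomal protein and the 20 highest genes, fold thresholds of 1.5 and 4, and the RIP input as control; leaving out genes that share exons, requiring both controls, and matching random lists on GC content or length were added after the data were seen. A count is said to have moved when it differs by more than 1.5 times, a log2 value by 0.585 or more and a correlation by 0.1 or more, because no replicate gives a spread.

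The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. They were tested on data simulated for si-LY6E-DT against si-NC from the real si-NC values, with known changes in some of the 10275 genes that passed the filter. At least 2-fold was called for 10.2% of genes changed 1.5-fold, 36.0% of those changed 2-fold, 83.3% of those changed 4-fold, 100% of those changed 8-fold and 0.615% of unchanged genes. Of genes changed 4-fold, 63.2% were called where si-NC was under 5 FPKM and 96.6% at 5 FPKM or more, since the pseudocount shrinks low genes. Of 27 lists of unchanged genes 1 was apart, and all 27 were after a shift of 0.5 on the log2 scale. The simulated noise was independent between genes. The check therefore cannot show how often a list stands apart when its members vary together between libraries. The noise was also normal on the log2 scale, with the same spread for every gene whatever its level. The 0.615% is thus not a rate of false calls in the real libraries.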

Results

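Gene expression was measured in MDA-MB-231 cells, a human triple-negative breast cancer line with mesenchymal features, in 5 RNA libraries, 1 per group. By its label, the si-LY6E-DT library comes from cells in which the long noncoding RNA LY6E-DT was targeted with a Smart Silencer. The treatment text pairs each target with the silencer of the other, and the labels of the libraries are followed here. The si-NC library is its negative control. Another library is labelled as a knockdown of HNRNPC, a nuclear protein that binds U-rich stretches of RNA. The remaining pair comes from RNA immunoprecipitation (RIP), in which RNA bound to HNRNPC was recovered from lysate with an antibody, and holds the immunoprecipitate and its input. The stated purpose was a comparative expression profile of the intended knockdowns and of HNRNPC-bound RNA. No group had a replicate, so no difference below has a replicate check, and no SD, SE or p-value is given. The files listed 11695 genes for si-LY6E-DT and for si-NC, 11755 for each RIP library and 11306 for the library labelled si-HNRNPC. The FPKM summed to 195673 (si-LY6E-DT), 195575 (si-NC), 272563 (input), 157407 (immunoprecipitate) and 227394 (labelled si-HNRNPC). The sequencing depth is unknown. Mitochondrially encoded mRNAs made up 29.8% of the FPKM sum in the RIP input, against 8.13% in si-LY6E-DT, 7.20% in si-NC, 9.05% in the immunoprecipitate and 9.92% in the library labelled si-HNRNPC. Across the 10731 genes listed in all libraries, Pearson's r of log2(FPKM + 1) was 0.970 between si-LY6E-DT and si-NC, 0.919 between the library labelled si-HNRNPC and the RIP input, and 0.863 between the library labelled si-HNRNPC and si-NC. Genes are not independent replicates, and these correlations describe the libraries only.

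The targeted genes were examined first. HNRNPC (ENSG00000092199.17_4; chromosome 14, 21209136 to 21269494, minus strand, GRCh38, protein-coding) was at 48.8 FPKM in the library labelled si-HNRNPC, against 52.2 in si-NC, 40.1 in si-LY6E-DT, 67.4 in the RIP input and 58.4 in the immunoprecipitate. Its log2 change was −0.10 against si-NC, and 90.6% of genes in that contrast changed at least as much. The level of the targeted mRNA therefore goes against the label, and every direction drawn from this library below is that of the library labelled si-HNRNPC. LY6E-DT (chromosome 8, 142981738 to 143018437, minus strand, GRCh38, annotated as a lincRNA) was not measured here, because the files hold almost only protein-coding genes, so its knockdown was not checked. Its neighbour LY6E (ENSG00000160932.10_4; chromosome 8, 143017982 to 143023832, plus strand, GRCh38), which encodes a membrane-anchored surface protein, was at 12.8 FPKM in si-LY6E-DT and 20.9 in si-NC, a log2 change of −0.66 that did not reach 2-fold. LY6E was at 4.24 FPKM in the library labelled si-HNRNPC, 1.69 in the RIP input and 0.638 in the immunoprecipitate. It thus fell by 2.06 on the log2 scale in the library labelled si-HNRNPC against si-NC but was 0.96 higher there against the RIP input.

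**Figure D1:**
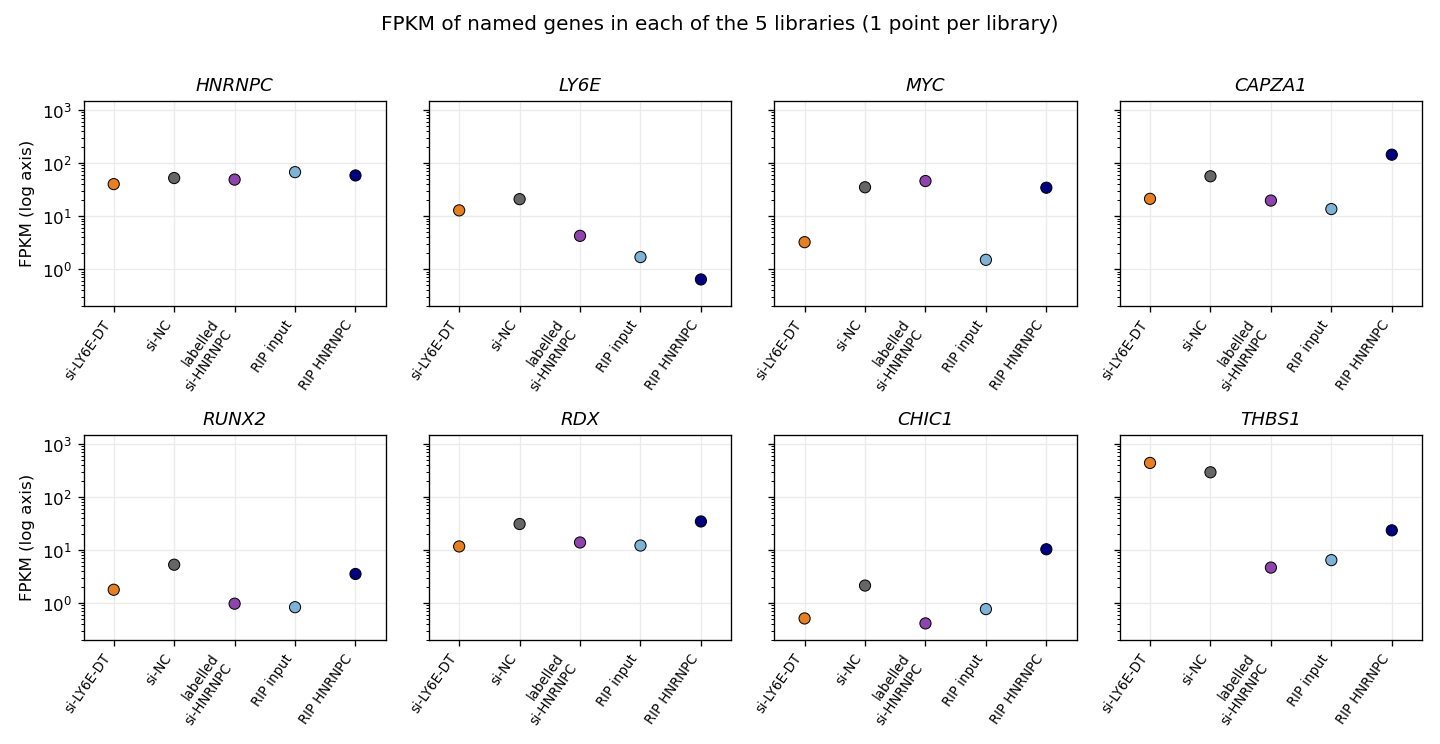
FPKM (log axis) of 8 genes in each of the 5 libraries, 1 point per library with no error bars because no group had a replicate. HNRNPC lies between 40.1 and 67.4 FPKM in all 5 libraries, while MYC is at 3.22 in si-LY6E-DT and 1.496 in the RIP input and at 34.9 in si-NC.

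The first comparison asks which mRNAs changed when LY6E-DT was targeted. NF-kB targets and genes of ATF4 and the unfolded protein response were higher as lists in si-LY6E-DT than in si-NC. The G2/M list was slightly lower, with no member reaching 2-fold. The transcription factor MYC was at 3.22 FPKM against 34.9 in si-NC. Of 10473 genes tested, 174 rose and 93 fell at least 2-fold. Among single genes outside shared loci, DAG1, the dystroglycan that links cells to the matrix, rose from 1.34 to 13.7 FPKM, and DDAH1, an enzyme that degrades methylated arginines, rose from 8.37 to 36.5. MYC fell by 3.09 on the log2 scale. The mucin-like membrane protein TMEM123 fell by 2.33, the beta-tubulin TUBB2B fell by 2.25, TMBIM1 fell by 1.71, and the nuclear import factor NUTF2 fell by 1.64. The reads behind these changes, including the about 10-fold differences of MYC and DAG1, were not examined here. The other named changes are uncertain, because 6 of the 8 largest rises and 3 of the 8 largest falls lay in genes that share exons with another gene on the same strand. These were TOMM6 (8.11 to 215 FPKM), RAD50 (1.52 to 13.8), RPL36A-HNRNPH2 (13.2 to 74.2), ZC3H11A (1.82 to 12.2), NBL1 (2.46 to 14.03), ZBED6 (14.5 to 1.65) and BCL2L2 (10.97 to 1.07). C7orf55-LUC7L2 was listed at 0 in si-NC and 11.99 FPKM in si-LY6E-DT, and MINOS1-NBL1 was listed at 0 in si-LY6E-DT and 13.4 in si-NC. With such genes left out, an alternative chosen after the data were seen, TXNIP, an inhibitor of thioredoxin, rose from 17.6 to 64.6 FPKM, MYADM rose from 11.6 to 46.1, and NR1D1, a nuclear receptor of the circadian clock, rose from 2.44 to 11.4. FSTL3 fell from 14.7 to 4.18 and the protease-activated receptor F2RL1 fell from 25.7 to 7.86. In that setting 54 genes fell.

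Of 28 gene lists with enough members, 9 had a median change in si-LY6E-DT apart from random lists of the same expression. Of 20 measured NF-kB targets, 8 rose and none fell, with a median log2 change of 0.66 (percentile 100 among 10000 random lists). IL1A rose from 2.25 to 7.72 FPKM, CXCL2 from 7.87 to 21.3 and TNFAIP3, an inhibitor of NF-kB signalling, from 6.25 to 16.4. Of 25 ATF4 and unfolded protein response genes, 6 rose and none fell (median 0.36, percentile 100). DDIT3, a transcription factor of the stress response that shares exons with another gene, rose from 5.31 to 23.1 FPKM, TRIB3 from 3.97 to 14.4 and SESN2 from 3.42 to 11.98. Among genes chosen after their values were seen, the endoplasmic reticulum chaperones HSPA5 (282 against 260.3 FPKM) and HSP90B1 (198 against 213) did not reach 2-fold. Of 20 immediate early genes, 3 rose and 1, MYC, fell (median 0.41, percentile 100). ATF3 rose from 1.33 to 5.61 FPKM, KLF4 from 3.67 to 11.3 and EGR1 from 0.498 to 2.58. Of 21 TGF-beta and SMAD targets, 2 rose and none fell (median 0.29, percentile 99.99). They were KLF10 (21.1 to 56.9 FPKM) and the receptor gene TGFBR1 (3.95 to 10.8), with JUNB at 19.2 against 9.88. Of 22 YAP/TAZ targets, 2 rose and none fell (median 0.14, percentile 98.04). They were GADD45A (55.2 to 120.3) and AJUBA (15.1 to 34.7, sharing exons), with LATS2 at 13.2 against 8.08. No member of the other 4 lists reached 2-fold. The 18 mesenchymal genes had a median of 0.19 (percentile 99.1; SNAI2 46.4 against 30.0 FPKM, TAGLN 16.05 against 11.4). The 13 mitochondrially encoded mRNAs had a median of 0.31 (percentile 99.99; MT-ND5 317 against 205, MT-ND1 1460 against 1029, MT-ND2 955 against 674). The 30 G2/M genes had a median of −0.24 (percentile 0.030; ANLN 68.1 against 104, TTK 11.5 against 17.2, KIF20A 23.4 against 34.1). The 38 nuclear-encoded oxidative phosphorylation genes had a median of −0.13 (percentile 2.47; ATP5A1 25.95 against 50.3, NDUFB1 14.9 against 28.99, COX6C 32.3 against 48.9).

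Lists within the range of random lists in si-LY6E-DT included the LY6 locus neighbours (6 members, median 0.25, percentile 89.7), the hnRNP family (24 members, −0.06, percentile 40.2), m6A writers, readers and erasers (18 members, 0.09, percentile 73.8), interferon-stimulated genes (21 members, −0.04, percentile 12.3) and p53 targets (22 members, −0.04, percentile 10.4). Heat shock (18 members, −0.09, percentile 23.2) and hypoxia genes (28 members, 0.03, percentile 64.7) were also within it, with no member reaching 2-fold. Markers of other cell types did not stand apart either, at percentile 72.0 for 6 luminal breast markers and 95.1 for 5 fibroblast markers, although the fibroblast markers reached 97.6 among random lists of the same transcript length. The filter left 3 leukocyte markers and no nuclear-retained lncRNA, too few to test. Across 10380 genes, which are not independent, the log2 change in si-LY6E-DT rose with transcript GC content (Spearman's rho 0.37). It fell with the A plus U content of the 3' UTR (rho −0.345). Matching the random lists on transcript GC content, chosen after the data were seen, brought the YAP/TAZ list to percentile 87.0 and the mesenchymal list to 96.7. In that setting 3 other lists became apart, namely KRAB zinc fingers (percentile 100, from 96.5), S phase genes (0.25, from 3.32) and ribosomal proteins (0, from 3.88). The KRAB list was also apart with a pseudocount of 0.1 (98.4), quantile normalization (97.7), rescaling (98.3) and matching on length (99.8). Quantile normalization brought the mitochondrially encoded mRNAs to 93.6, and a pseudocount of 5 brought oxidative phosphorylation to 3.04. Against the RIP input in place of si-NC the G2/M list turned to percentile 100, the mitochondrially encoded list to 0, and the ATF4 and immediate early lists were no longer apart (82.4 and 14.2). Newly apart and higher there were epithelial genes (99.85), matrix genes (99.8) and KRAB zinc fingers (99.7). Cholesterol synthesis (0), histones (0.010) and apoptosis regulators (2.035) were newly apart and lower. In the G2/M, mitochondrially encoded, epithelial, KRAB, cholesterol, histone and apoptosis lists, si-NC itself differed from the input the same way, as given below. This change of control therefore carries the difference between si-NC and the input, and cannot show whether the changes against si-NC hold.

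**Figure D2:**
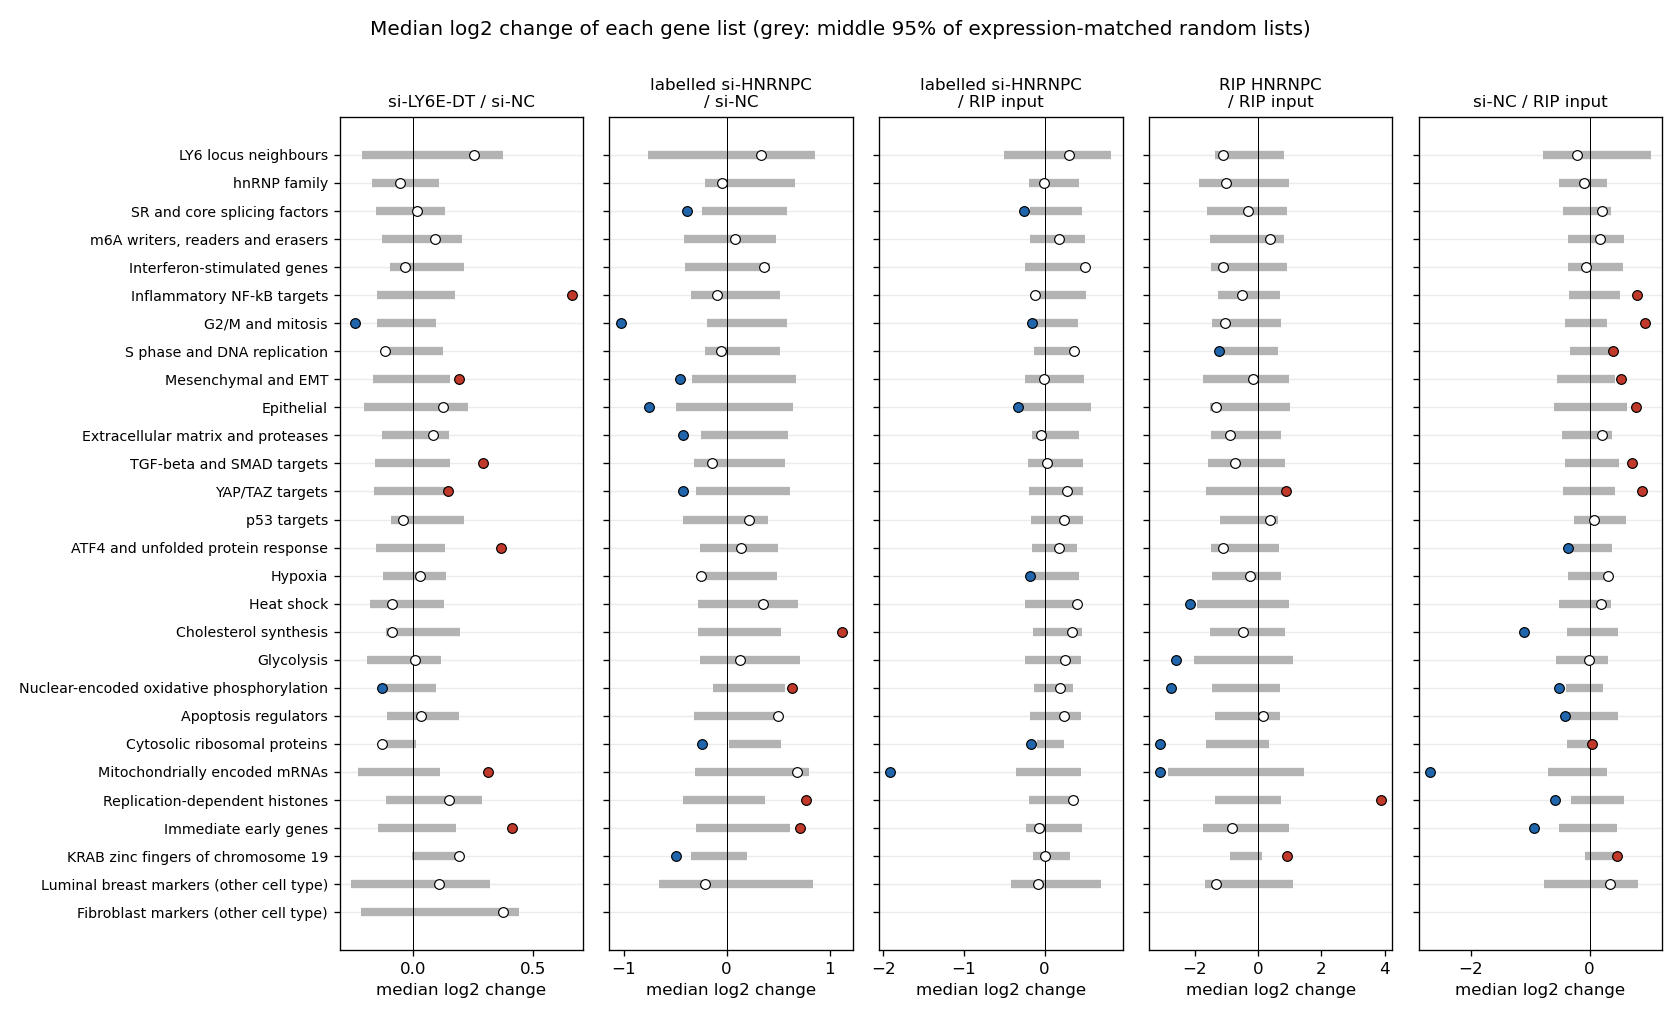
Median log2 change (horizontal axis, 1 panel per contrast with its own scale) of each gene list with at least 5 members; grey bars hold the middle 95% of the random lists, and red or blue points are lists above or below it while white points are within. The NF-kB targets stand at 0.66 in si-LY6E-DT against si-NC, the G2/M list at −1.03 in the library labelled si-HNRNPC against si-NC, and the histones at 3.89 in the immunoprecipitate against input.

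The second comparison asks which mRNAs changed when HNRNPC was targeted. The only library labelled as a negative control is si-NC, and the label of the targeted library is not borne out by its HNRNPC level. The library labelled si-HNRNPC had less mRNA of matrix and protease genes and of mitotic genes than si-NC, and more of cholesterol synthesis, oxidative phosphorylation and histone genes. Thrombospondin THBS1 fell from 291 to 4.64 FPKM (log2 −5.69). ANGPTL4 fell from 42.7 to 0.941, the nonmuscle myosin MYH10 from 26.6 to 0.738 and collagen COL7A1 from 23.1 to 0.517. NNMT fell from 58.7 to 2.85, SCG5 from 20.1 to 0.652 and the acute-phase gene SAA1 from 419.5 to 33.8. The cancer-testis gene SPANXB1 rose from 5.81 to 1094 FPKM (log2 7.33), the collagenase MMP1 from 2.498 to 170.4 and the stress cytokine GDF15 from 0.257 to 36.1. EMP1 rose from 1.86 to 64.2, LCP1 from 4.96 to 95.4, and ESAM from 2.08 to 46.6, as did TOMM6 (8.11 to 244) and TM4SF19 (1.49 to 46.8), which share exons. The RIP input, whose label names no knockdown, was close to this library in many of these genes. There THBS1 was at 6.41 FPKM, ANGPTL4 at 0.911, MYH10 at 0.502, SPANXB1 at 1580, MMP1 at 149.9, GDF15 at 28.9 and EMP1 at 86.5. In the input SAA1 (110 FPKM) and LCP1 (36.4) lay between si-NC and the library labelled si-HNRNPC. Against si-NC, 1275 of 10247 genes rose and 967 fell at least 2-fold, so that 56.9% of the changed genes rose. That share became 40.1% (1207 rising, 1802 falling) when each library was rescaled without mitochondrial, ribosomal protein and the 20 highest genes, which moved the median change from 0.04 to −0.14.

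Of 27 lists, 12 stood apart in the library labelled si-HNRNPC against si-NC. Of 30 G2/M genes 16 fell and none rose (median −1.03, percentile 0). CENPF fell from 71.1 to 9.61 FPKM, CENPE from 21.0 to 2.86 and HMMR from 6.88 to 0.765. Of 24 matrix and protease genes 10 fell and 3 rose (−0.43, percentile 0.20; COL5A1 37.4 to 2.56 FPKM). Of 17 mesenchymal genes 8 fell and 1 rose (−0.45, percentile 0.635; FN1 82.7 to 7.82, TGFBI 22.4 to 3.10). Of 11 epithelial genes 5 fell and 2 rose (−0.75, percentile 0.260; KRT7 129 to 13.7, KRT19 85.0 to 9.58, CLDN4 13.4 to 1.303). Of 21 YAP/TAZ targets 5 fell and none rose (−0.42, percentile 0.540; GADD45A 55.2 to 9.21, F3 129 to 29.9, PTPN14 12.6 to 2.20). Of 24 SR and core splicing factors 4 fell and none rose (−0.39, percentile 0.380). SRSF11 fell from 13.8 to 5.18, CLK4 from 3.19 to 0.762 and CLK1, a kinase of SR proteins, from 15.1 to 6.32. Of 36 KRAB zinc fingers of chromosome 19, 4 fell and none rose (−0.50, percentile 0.030; ZNF83 4.44 to 0.988). Of 77 ribosomal protein genes 5 rose and 3 fell, with a median of −0.24 (percentile 0; RPS27A 397 to 113 FPKM). Of 24 cholesterol synthesis genes 13 rose and none fell (1.12, percentile 100). INSIG1 rose from 9.73 to 48.0 FPKM, FDFT1 from 5.57 to 24.2 and MSMO1 from 15.8 to 60.8. Of 38 oxidative phosphorylation genes 12 rose and none fell (0.64, percentile 99.0; ATP5C1 62.2 to 173). Of 18 histone genes 8 rose and none fell (0.77, percentile 99.99; HIST1H2BK 43.0 to 276). Of 18 immediate early genes 7 rose and none fell (0.71, percentile 99.1; DUSP4 6.56 to 66.2, DUSP5 9.17 to 71.0, KLF2 2.57 to 14.4). Random lists of the same GC content, chosen after the data were seen, brought the splicing factors to percentile 3.31 and the KRAB zinc fingers to 6.96. Random lists of the same length brought matrix genes to 6.05, YAP/TAZ targets to 3.23 and histones to 94.8, and the immediate early genes were at 96.2 without the filter.

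Against the RIP input, whose label names no knockdown, the library labelled si-HNRNPC showed a different set of changes, with 928 genes higher and 410 lower at least 2-fold among 10185. MYC rose from 1.496 to 45.8 FPKM, the thioredoxin reductase TXNRD1 from 9.46 to 147, the cell cycle inhibitor CDKN1A from 1.48 to 31.9, PRKAR1A from 3.23 to 40.3 and PEA15 from 25.7 to 323. The salivary cystatins CST1 and CST4 fell from 56.0 to 1.12 and from 42.3 to 2.44. LXN fell from 49.3 to 5.73, IGFBP1 from 36.5 to 4.57 and MT-CYB from 6083 to 980.3. In most of these genes si-NC differed from the input in the same direction. There MYC was at 34.9 FPKM, TXNRD1 at 109, CDKN1A at 19.7, PRKAR1A at 27.4 and MT-CYB at 333. CST1 was at 0.556 in si-NC, CST4 at 0.539, LXN at 5.54 and IGFBP1 at 6.11, while PEA15, at 22.0, was near the input. Only 6 lists stood apart against the RIP input, all lower. They were the SR and core splicing factors (−0.26, percentile 0.785; CLK1 15.6 to 6.32 FPKM), G2/M (−0.15, percentile 2.07), epithelial genes (−0.34, percentile 1.36), hypoxia genes (−0.18, percentile 1.62; BNIP3L 45.7 to 9.58), ribosomal proteins (−0.17, percentile 0.375) and mitochondrially encoded mRNAs (−1.92, percentile 0). Cholesterol synthesis (percentile 86.8), oxidative phosphorylation (70.3), histones (93.5), immediate early genes (13.3), YAP/TAZ targets (79.0), mesenchymal genes (22.2), matrix genes (10.96) and KRAB zinc fingers (24.2) were not apart from random lists. Against both controls, a comparison added after the data were seen, 243 genes rose and 114 fell, where independent lists would share 119 and 32.5. Both comparisons share the library labelled si-HNRNPC, so part of that excess may come from it. In genes picked from that table after their values were seen, PEA15 was at 323 FPKM against 22.0 in si-NC, RAB32 at 173 against 28.7 in si-NC and 21.4 in the input. RAB8B was at 1.38 against 10.8 and 11.3, the chaperone HSP90B1 at 58.4 against 213 and 234, RND3 at 10.0 against 43.1 and 50.5, and YWHAB at 20.8 against 69.1 and 90.1. These libraries' gene tables were listed separately, so levels set across them rest on the FPKM scale alone.

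The third comparison asks which mRNAs were recovered with HNRNPC. Replication-dependent histone mRNAs and long mRNAs were enriched in the immunoprecipitate over input. Short mRNAs, and mRNAs of ribosomal protein, nuclear-encoded oxidative phosphorylation and glycolysis genes, were depleted. Mitochondrially encoded mRNAs were also lower than in the input, where their share was above that of every other library. The histone gene HIST1H3B rose from 0.955 to 122 FPKM, HIST1H3C from 1.35 to 140.0 and HIST1H2AH from 0.714 to 104. HIST1H3B and HIST1H3C were also low in si-LY6E-DT (1.01 and 1.67 FPKM), si-NC (0.874 and 1.32) and the library labelled si-HNRNPC (2.42 and 1.92). Their high level was thus seen in the immunoprecipitate library only, and its cause was not tested. PDP1, a phosphatase that activates pyruvate dehydrogenase, rose from 0.656 to 127 (log2 6.27) and the RNA-binding protein gene PTBP3 from 0.150 to 70.7. ZC3HAV1L rose from 0.335 to 62.2 and ZNF460 from 0.259 to 54.1. In si-NC these genes were at 6.03, 11.5, 7.13 and 1.47 FPKM in that order, above the input and below the immunoprecipitate. Their ratios thus also carry a low input level. NUDT4P1 was listed at 0 in the input and 40.7 FPKM in the immunoprecipitate. Kisspeptin KISS1 fell from 295 to 4.38 FPKM (log2 −5.78), the respiratory complex assembly factor NDUFAF2 from 109 to 1.84, CHCHD2 from 278 to 7.84. The mitochondrial ribosomal proteins MRPL54 and MRPL14 fell from 47.1 to 0.669 and from 161 to 4.97, SH3BGRL3 from 117 to 3.23 and CST4 from 42.3 to 0.574. NME1-NME2 (209.6 to 3.36) shares exons. In all, 2486 of 10284 genes were enriched and 3791 depleted at least 2-fold, so that 39.6% of the changed genes were enriched. The median change was −0.34, and centring on it made the share 50.8% (3121 enriched, 3027 depleted).

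Of 27 lists, 9 stood apart in the immunoprecipitate. Of 34 histone genes 32 were enriched and none depleted (median 3.89, percentile 100). Of 42 KRAB zinc fingers 20 were enriched and none depleted (0.92, percentile 100; ZNF850 0.6705 to 9.29 FPKM), but the percentile was 61.0 among random lists of the same transcript GC content, an alternative added after the data were seen. Of 22 YAP/TAZ targets 11 were enriched and 2 depleted (0.88, percentile 97.98; NT5E 43.0 to 350 FPKM, TGFB2 5.95 to 47.1), with percentiles down to 96.96 in other settings. Of 77 ribosomal protein genes 76 were depleted and none enriched (−3.09, percentile 0; RPS18 717 to 32.2 FPKM, RPL8 325 to 14.1). Of 38 oxidative phosphorylation genes 35 were depleted and 1 enriched (−2.74, percentile 0; UQCRH 218 to 10.0, NDUFA1 169 to 8.01, COX6B1 133 to 4.15). Of 19 glycolysis genes 14 were depleted and none enriched (−2.59, percentile 0.170; TPI1 281 to 11.9, PKM 173 to 11.98, ENO1 535 to 42.9). Of 18 heat shock genes 13 were depleted and 1 enriched (−2.15, percentile 0.960; HSP90AB1 994 to 91.3). Of 32 S phase genes 19 were depleted and 2 enriched (−1.23, percentile 2.46; MCM7 50.8 to 4.66, E2F1 24.97 to 2.502), the last reaching percentile 3.96 with a pseudocount of 0.1. Of 13 mitochondrially encoded mRNAs 12 were depleted (−3.10, percentile 1.34), with MT-CYB falling from 6083 to 480.3. The percentile was 26.8 after quantile normalization and 4.325 with a mean FPKM of at least 5. Their share of the FPKM sum in the immunoprecipitate (9.05%) was near that in si-NC (7.20%), and MT-CYB was at 333 in si-NC. This depletion thus rests on the high share in the input (29.8%). Some lists were apart only in alternatives. They were G2/M (percentile 0.020) and p53 targets (98.07) matched on GC content, and matrix genes (0.070) matched on length. With a mean FPKM of at least 5, epithelial genes (0.080) and p53 targets (99.7) were apart, as were epithelial genes without the filter (1.61). Across genes, the log2 ratio rose with transcript length (Spearman's rho 0.56 across 10219 genes, which are not independent). It went from a median of −1.85 in the shortest 20% of genes to 1.07 in the longest, and was lower at higher transcript GC content (rho −0.55). Enrichment here is over input only; an IgG control was not analysed here.

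**Figure D3:**
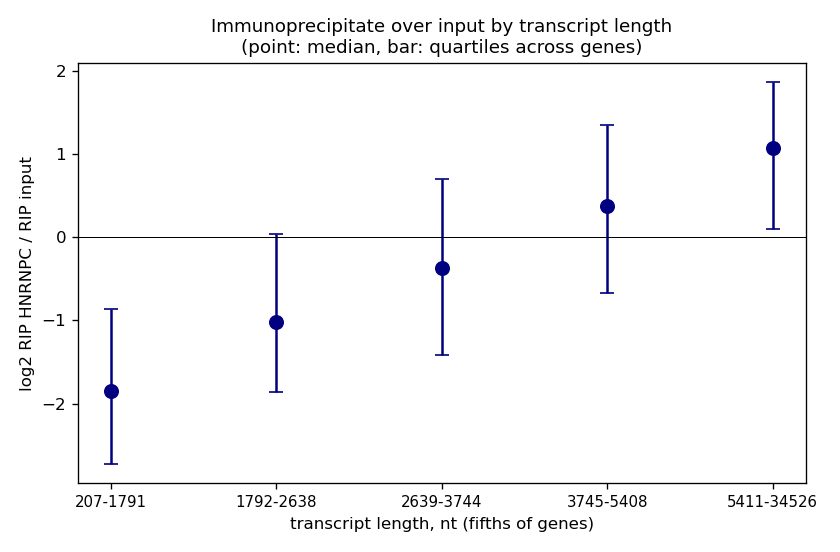
Log2 ratio of the HNRNPC immunoprecipitate over input (vertical axis) in 5 equal groups of genes by annotated transcript length in nucleotides (horizontal axis); points are medians and bars are quartiles across genes. The median rises from −1.85 in the shortest group to 1.07 in the longest.

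The fourth comparison, si-NC against the RIP input, shows how far libraries of the same cell line with no targeted gene differed in this series. THBS1 was at 291 FPKM in si-NC and 6.41 in the input, ANGPTL4 at 42.7 and 0.911, PMEPA1 at 36.3 and 0.715. The carbonic anhydrase CA9 was at 51.8 and 1.49, SLC25A24 at 39.1 and 0.893, MYH10 at 26.6 and 0.502, and BST2 at 73.2 and 3.61. SPANXB1 was at 5.81 FPKM in si-NC and 1580 in the input, the cytokine IL1B at 0.917 and 89.4, MMP1 at 2.498 and 149.9. CST1 was at 0.556 and 56.0, EMP1 at 1.86 and 86.5, CST4 at 0.539 and 42.3, HMGN5 at 0.771 and 42.0, and GDF15 at 0.257 and 28.9. In all, 1457 of 10264 genes were higher and 1068 lower, a share of 57.7% higher that became 47.8% after centring on the median of 0.11. Of 27 lists, 16 stood apart. Those higher in si-NC were G2/M (14 of 30 higher, none lower, median 0.93; ANLN 104 against 21.0 FPKM), YAP/TAZ targets (9 of 21 higher and 1 lower, 0.88), and NF-kB targets (7 of 21 higher and 5 lower, 0.79, with a mean of 0.13; IL6 25.1 against 5.43). So were epithelial genes (5 of 10 higher and 1 lower, 0.78; KRT7 129 against 13.8), TGF-beta targets (9 of 21 higher and 2 lower, 0.71), mesenchymal genes (6 of 16 higher and 2 lower, 0.53; FN1 82.7 against 6.97), KRAB zinc fingers (6 of 40 higher, none lower, 0.45), S phase genes (7 of 32 higher and 3 lower, 0.39) and ribosomal proteins (2 of 77 higher and 7 lower, 0.04, with a mean of −0.03 and a median of −0.08 after centring). Those lower were mitochondrially encoded mRNAs (12 of 13 lower, none higher, −2.69), cholesterol synthesis (14 of 24 lower and 1 higher, −1.11; INSIG1 9.73 against 57.5 FPKM), immediate early genes (9 of 19 lower and 2 higher, −0.94; DUSP4 6.56 against 81.2), and histones (6 of 16 lower, none higher, −0.58). So were oxidative phosphorylation (8 of 38 lower and 1 higher, −0.52), apoptosis regulators (4 of 23 lower and 2 higher, −0.41; BAX 24.9 against 65.7) and ATF4 targets (9 of 27 lower and 4 higher, −0.37). With a mean FPKM of at least 5, S phase (percentile 93.8), mesenchymal (95.7), TGF-beta (37.4), ATF4 (12.3) and apoptosis (8.12) lists were not apart, nor were epithelial genes without the filter (97.2). Among random lists of the same GC content, ribosomal proteins were at percentile 34.8, KRAB zinc fingers at 95.8 and histones at 3.48, the last reaching 30.7 among lists of the same length.

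The changes of the targeted libraries were then compared with each other. Across 9998 genes the log2 changes of si-LY6E-DT and of the library labelled si-HNRNPC, both against si-NC, had Pearson's r of 0.26 and Spearman's rho of 0.24. In all, 61 genes rose in both and 30 fell in both, where independent lists would share 16.4 and 8.22. Both changes use the same si-NC library, so independence is not the fitting reference. Libraries simulated with no shared change but a shared control, with the spread of each contrast kept and 50% of the variance of si-LY6E-DT against si-NC assigned to si-NC, gave a mean r of 0.22 over 100 draws (0.20 to 0.24) and shared 43.6 rises and 31.3 falls. That assignment is an assumption, and the simulation was added after the data were seen. With the RIP input as the control of the library labelled si-HNRNPC, r was 0.06 and 25 genes rose and 7 fell in both, where independent lists would share 13.8 and 3.02. With the RIP input as the control of si-LY6E-DT instead, r was −0.61 and 22 genes rose and 12 fell in both, where independent lists would share 199 and 94.8. That last pairing shares no library. Its r is, with the sign turned, the r of 0.61 between the RIP input over si-LY6E-DT and the library labelled si-HNRNPC over si-NC. It therefore cannot be told apart from a difference between those sets of libraries. Where both changes use si-NC, that single control library cannot be split, and most of the overlap may come from it.

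The last comparisons ask whether mRNAs enriched in the HNRNPC immunoprecipitate over input changed in the targeted libraries. Enrichment does not by itself show binding, because it also varied with transcript length and GC content. Genes enriched at least 2-fold in the immunoprecipitate had a median change of −0.06 in si-LY6E-DT (2247 genes) and −0.19 in the library labelled si-HNRNPC (2238 genes), both against si-NC and both at percentile 0 among random lists of the same expression. Depleted genes had medians of 0.07 and 0.31, both at percentile 100. Against the RIP input, which also enters the enrichment ratio, both percentiles of the enriched genes turned to 100. When the random lists were matched on transcript GC content, an alternative added after the data were seen, the percentiles were 90.4 and 11.8, whereas matching on length left them at 0 and 0.020. The rank correlation of the change with the enrichment ratio was −0.13 and −0.26, became 0.0925 and −0.0933 with GC content held fixed, and 0.016 and 0.021 with GC content and length held fixed. Of 9465 genes, 23 were at least 2-fold lower in both si-LY6E-DT and the library labelled si-HNRNPC, and 4 of these were enriched in the immunoprecipitate. If the 23 genes were independent of the 2198 enriched genes, 5.34 would be shared. That reference takes the 23 as given, although both changes use the same si-NC library. The 4 genes were CAPZA1, a capping protein of actin filaments (56.4 FPKM in si-NC, 21.2 in si-LY6E-DT, 19.6 in the library labelled si-HNRNPC, 13.6 in the input and 144 in the immunoprecipitate), the transcription factor RUNX2 (5.26, 1.77, 0.968, 0.831 and 3.52 FPKM in that order), RDX, which encodes radixin, a linker of actin to the membrane (30.8, 11.6, 13.8, 12.1 and 34.4 FPKM), and CHIC1 (2.13, 0.510, 0.411, 0.765 and 10.3 FPKM). The count of such genes was 0 with the RIP input as control of the library labelled si-HNRNPC, and 13 with a pseudocount of 0.1.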

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

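Leaving out genes that share exons, requiring both controls, the RIP input as control of only the library labelled si-HNRNPC in the intersection, and matching random lists on transcript GC content or length were chosen after the results were seen. No paired analysis was possible because each group holds 1 library. Depth is unknown, which limits what can be said of genes near 1 FPKM, and where no value shows otherwise the cause of a difference was not tested. Thresholds, pseudocounts and filters change counts by construction.

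For si-LY6E-DT against si-NC (174 rising, 93 falling) the counts were 330 and 150 with a pseudocount of 0.1, 42 and 30 with 5, 79 and 59 with a mean FPKM of at least 5, 319 and 140 after rescaling, 662 and 371 at 1.5-fold, 22 and 16 at 4-fold, 1653 and 1032 with the RIP input as control, and 54 falling without genes that share exons. For the library labelled si-HNRNPC against si-NC (1275 and 967) they were 618 and 324 with a pseudocount of 5, 634 falling with a mean FPKM of at least 5, 1802 falling after rescaling, 2604 and 2131 at 1.5-fold, 176 and 98 at 4-fold, 410 falling with the RIP input as control, and 243 and 114 against both controls. For the immunoprecipitate (2486 and 3791) they were 1520 and 2238 with a pseudocount of 5, 2394 depleted with a mean FPKM of at least 5, and 956 and 1750 at 4-fold. For si-NC against the RIP input (1457 and 1068) they were 518 and 505 with a pseudocount of 5, 841 higher with a mean FPKM of at least 5, 2863 and 2143 at 1.5-fold, and 226 and 180 at 4-fold. The other counts stayed within 1.5 times.

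The 4 genes of the intersection became 13 with a pseudocount of 0.1, 1 with 5, 2 with a mean FPKM of at least 5, 8 after centring, 9 after quantile normalization, 17 after rescaling, 46 at 1.5-fold, 0 at 4-fold and 0 with the RIP input as control of the library labelled si-HNRNPC. The correlation of the changes of both targeted libraries went from 0.26 to 0.0555 with the RIP input as control of the library labelled si-HNRNPC and to −0.61 with it as control of si-LY6E-DT, and the lists apart in the library labelled si-HNRNPC went from 12 to 6 with the RIP input as its control. With the RIP input as control the percentile of genes enriched in the immunoprecipitate reversed from 0 to 100 in si-LY6E-DT and from 0 to 100 in the library labelled si-HNRNPC. Matched on GC content it was 90.4 and 11.8, and matched on length 0 and 0.020. In si-LY6E-DT the G2/M list reversed to percentile 100 and the mitochondrially encoded list to 0 with the RIP input as control. Since si-NC differed from the input the same way in both lists, these reversals carry that difference between libraries. Of the list percentiles under all alternatives, 930 kept their side of the thresholds, 53 no longer stood apart, 37 newly did and 2 reversed. The HNRNPC change stayed within the stated limit in every alternative run.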

Other observations

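The tests of read trading between gene models, of the HNRNPC level and of the U-run part of the input library, and the MYC target list, were chosen after the results were seen.

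MYC was at 3.22 FPKM in si-LY6E-DT, 34.9 in si-NC, 45.8 in the library labelled si-HNRNPC, 1.496 in the RIP input and 34.3 in the immunoprecipitate. A list of 40 MYC targets, written after that value was seen, had a median log2 change of −0.07 in si-LY6E-DT against si-NC, with 1 gene rising and none falling (percentile 18.3 among random lists). Against the RIP input in place of si-NC, 6 rose and 2 fell (percentile 98.3). For si-NC itself against the input, 4 were higher and 2 lower (percentile 95.1), so much of that value may come from the input. In the immunoprecipitate 28 of the 40 were depleted and 1 enriched (median −2.15, percentile 0). The random lists for this list were matched on expression only, not on transcript length or GC content.

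Large changes between si-LY6E-DT and si-NC gathered at overlapping genes. Of 38 genes changed at least 4-fold, 68.4% share exons with another gene, against 10.3% of all genes tested. Among 22 groups with a member changed at least 4-fold, 18 had a partner changing the opposite way, and the median absolute log2 change of the summed FPKM was 0.32, against 0.66 had only that member changed. In the 8 groups where the member made up at least 50% of the sum these were 0.7111 and 1.72. The summed FPKM of the group of TOMM6 (217 in si-LY6E-DT and 27.7 in si-NC) and of a group that holds SPPL2B (74.99 and 212) changed over 2-fold. In the latter a member without a symbol fell, while SPPL2B itself was at 6.05 FPKM against 3.31 in si-NC. Reads assigned to a gene model in one library and to its neighbour in the other may thus explain a part, but the question stays open. The share of genes changed at least 2-fold was 1.4783 times higher at a mean of 1 to 5 FPKM than above, which leaves a part for noise of low genes open, as is an effect of targeting LY6E-DT.

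The library labelled si-HNRNPC differed from si-NC in many genes while HNRNPC did not. Of 2198 genes changed at least 2-fold, 46.1328% also differed at least 2-fold the same way between the RIP input and si-LY6E-DT, libraries outside that contrast, and 1.55% the opposite way; of 265 genes changed 4-fold, 80.0% did so the same way. The log2 change of HNRNPC was −0.4589 against the RIP input and 0.28 against si-LY6E-DT. A difference between culture or library sets and an effect of the treatment cannot be told apart here, because the only control labelled as such lies in the other set and each group has 1 library. A lower HNRNPC protein level without a lower mRNA, or a mislabelled library, may also apply and was not tested.

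The ratio of immunoprecipitate to input varied with transcript features. Longer mRNAs had higher ratios with U-run density held fixed (partial rank correlation 0.5124), which could come from recovery by length alone. The density of runs of 5 U in the 3' UTR kept a partial rank correlation of 0.2662 with length, A-run density and A plus U content held fixed. A runs had −0.01. Transcript GC content (rho −0.55 with the ratio) and 3' UTR length (rho 0.58) were not held fixed, so the U-run value may carry part of these. Binding at U tracts stays a hypothesis. The input library might explain part of the length trend, since si-NC over the input also rose with length (0.3105) but the library labelled si-HNRNPC over the input hardly did (0.0377), so this stays open. For the U-run part the tables argue against it, as the larger of the corresponding values was −0.0162.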
